A study of Mus musculus with 6 samples.

How the data were processed

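RNA was measured by bulk RNA-seq in 6 libraries of Hepa1-6 cells, a mouse liver cancer line: 3 from cells whose Matr3 gene had been knocked out with CRISPR/Cas9 and 3 from wild-type cells. Groups and replicate numbers were taken from the sample titles and the genotype labels. The labels do not say whether the 3 libraries of a group came from separate cultures or, for the knockout, from separate clones, so p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, RNA was purified with a column kit and libraries were made with an mRNA-seq kit; strandedness is not stated.

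The authors deposited a single table for the whole series, with 55573 rows. Its raw counts per gene are whole numbers, per the file headers and the values, and were used as deposited. The deposited FPKM values equal the count divided by gene length and by a library size that lies between 0.970 and 1.05 times the column's total count. The deposited signal, 1 mean of scaled counts per group, the deposited log2 fold changes and the deposited p-values belong to the authors' own comparison, whose tool is not given in the sources used here. The deposited log2 fold change was smaller in size than the log2 ratio of the deposited means in 2464 of the 2464 genes that the authors' table calls and that have a finite ratio, so it has been shrunken. Aligner, counter and annotation release are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, 2 names for 1 assembly. The scaffold names in the table belong to the later build GRCm39, and of the 52081 gene identifiers also present in the GENCODE M21 annotation of GRCm38, 1494 have the same coordinates there. These values argue against GRCm38 as the build of the coordinates, in conflict with the processing notes. Coordinates are given as the table has them, and the annotation release that they come from could not be settled. The 159 rows named as unannotated features took 0.242% of the counts and stayed in the tests.

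Library totals ranged from 20736570 to 30794032 counts. A gene with 0 counts in a group was given a floor of 3 counts over the group's 3 libraries, and ratios with 1 to 3 counts are given with an exact 95% counting interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

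Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14842 of the 27065 genes with a count in any library, libraries were scaled by TMM, and the quasi-likelihood F test compared knockout with wild type with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the tested genes and called under 0.05. Fold changes are knockout over wild type on the log2 scale, and standard errors (SE) follow from the F statistic. CPM values are counts scaled to the TMM-adjusted library size, with the SD over 3 libraries.

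Before the data were examined, 34 gene lists were fixed for the pathways, cell types and complexes that suit a liver cancer line and an RNA-binding protein. Of these, 33 had at least 5 tested members and were compared with all other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01. Each list was also tested with an estimated correlation and with fry, which asks whether the list's own genes move 1 way on balance. The genes named were chosen by a rule fixed at the same time: Matr3 and Dhx58; the 8 largest rises and the 8 largest falls among called protein-coding genes with a mean of at least 5 CPM, an established symbol and no overlap between the groups; up to 4 members with the smallest p from each of 4 lists on interferon, RNA sensing and antigen presentation; and up to 3 from every other list that passed. Other names were chosen after their values were seen, and are said to be. A few genes that the rule or the lists would name are not reported here.

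The scripts were tested on simulated counts for the comparison of knockout with wild type, made from the real means, library sizes and dispersions. The 200 changed genes were drawn only from genes above a limit on expression, so the recovery does not cover the lowest tested genes. Of the changed genes, 98.5% were recovered at a fold of 4, 86.6% at a fold of 2 and 37.3% at a fold of 1.5, among 14624 genes. Over 10 such draws, 4.32% to 10.7% of the calls were false, with a mean of 7.53%, above the nominal 5%. Genes were simulated independently of each other, with no GC trend and no library standing apart, so this false share need not hold for these libraries.

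Alternatives were RLE size factors, library totals alone, no filter on low counts, a mean of at least 1 CPM, protein-coding genes only, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma voom, limma on log2(FPKM + 1), and a stricter adjusted p of 0.01. Added after seeing the data were the removal of the per-library trend with GC content and transcript length, and a fit without knockout library 2 and wild-type library 1. GC content and length came from the longest GENCODE M21 transcript, found for 98.8% of tested genes. Windows of 40 neighbouring genes with a log2 CPM over 2 were scanned along the chromosomes. Figures were drawn with matplotlib 3.10.9.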

Results

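Gene expression was measured in 3 Matr3 knockout and 3 wild-type libraries of Hepa1-6 cells, a line derived from a mouse liver tumour. Matr3 encodes matrin 3, an RNA- and DNA-binding protein of the nuclear matrix. The comparison asks what differs in the libraries labelled as Matr3 knockout, with attention to Dhx58 and the type I interferon response, which the series title names. The knockout libraries held 23126778, 30794032 and 28551184 counts and the wild-type libraries 20736570, 27578804 and 26935129. Within groups, knockout libraries 1 and 3 were closest (chi-square of 3.46 per gene), while knockout library 2 stood at 55.5 and 66.1 from them. Wild-type libraries 2 and 3 differed by 6.29 per gene, and wild-type library 1 by 23.3 and 27.5 from them. Across groups, knockout library 2 stood at 48.1 from wild-type library 3, and knockout library 1 at 42.8 from wild-type library 1. This distance therefore did not separate the groups. The correlation of log2 CPM did, with values from 0.982 within groups and up to 0.974 across them. All pairs differed by more than counting noise, which says nothing on whether libraries share an RNA sample or a culture.

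Libraries also differed in composition. Across genes, which are not independent replicates, a library's deviation from the mean correlated with GC content at 0.26 in knockout libraries 1 and 3 and at -0.27 in knockout library 2, against -0.03, -0.03 and -0.16 in the wild-type libraries. Wild-type library 1 had 23440 genes with counts against 20450 to 21217 in the others, and 0.717% of its counts on long noncoding RNAs against 0.354% to 0.430%.

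Matr3 mRNA fell in the knockout but was not lost. Matr3 (ENSMUSG00000037236; chromosome 18, 35695191 to 35726888, plus strand) was at 76.0, 86.1 and 75.3 CPM in the knockout libraries and at 129, 125 and 134 CPM in the wild-type libraries. The means were 79.1 ± 6.08 and 129 ± 4.65 CPM (SD, n = 3 each), a log2 fold change of -0.71 (SE 0.0899, edgeR quasi-likelihood adjusted p = 0.00270). The counts are per gene and do not show the edited site, and a transcript annotated as Snhg4 (ENSMUSG00000117694) overlaps Matr3 on the same strand. Dhx58, which encodes the RIG-I-like receptor LGP2, rose 1.90-fold. Dhx58 (ENSMUSG00000017830; chromosome 11, 100585710 to 100595097, minus strand) was at 9.75 ± 0.327 CPM in the knockout and 5.13 ± 0.805 CPM in the wild type (SD, n = 3 each), a log2 fold change of 0.93 (SE 0.156, edgeR quasi-likelihood adjusted p = 0.00745). The authors' deposited table gives log2 fold changes of -0.67 for Matr3 and 0.81 for Dhx58.

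**Figure D1:**
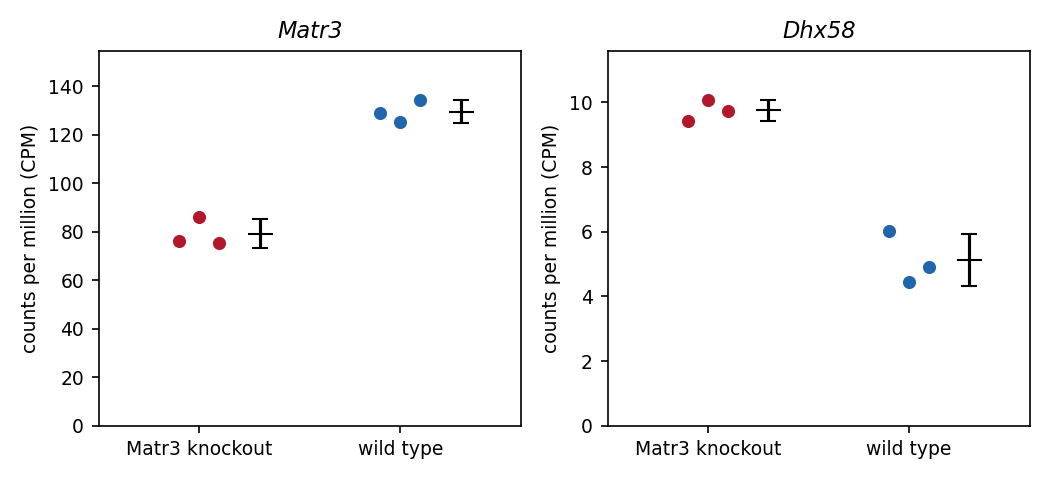
Levels (CPM) of Matr3 and Dhx58 in each library (points), with the group mean and SD at the right of each group (n = 3). Matr3 lies at 75.3 to 86.1 CPM in the knockout libraries and 125 to 134 CPM in the wild-type libraries, and Dhx58 at 9.43 to 10.1 CPM against 4.45 to 6.02 CPM.

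Between the libraries labelled knockout and wild type, 2252 of 14842 tested genes changed, 15.2%, of which 1142 rose and 1110 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 564 changed at least 2-fold, 243 upward and 321 downward, and the median size of the log2 fold change among the called genes was 0.62. The deepest fall was that of Grb10, an adaptor that restrains insulin and growth factor signalling, with 6 reads in the 3 knockout libraries against 16133 in the wild type, a 2998-fold lower level. Pla2g4a, the cytosolic phospholipase that frees arachidonic acid, fell 24.1-fold (log2 fold change -4.59) and the water channel gene Aqp1 10.1-fold (-3.33). Further falls were those of the death receptor gene Tnfrsf21 (-2.90), Tenm4 (-2.61), the semaphorin Sema3f (-2.61) and Trp53i11 (-2.59). The largest rises under the naming rule were Mlph, which links melanosomes to their motor, at 4.55-fold (log2 fold change 2.18), Glt8d2 at 3.96-fold (1.98), Galnt15 at 3.82-fold (1.93) and the ephrin receptor Epha4 at 3.55-fold (1.82). Ifnlr1, the receptor subunit for interferon lambda, rose 3.46-fold (1.79), followed by the homeobox gene Barx2 (1.79), the desmosome gene Dsp (1.72) and the lysophosphatidic acid receptor Lpar3 (1.71). The naming rule required of these 15 genes a call and every knockout library on 1 side of every wild-type library, so neither is a result. Their edgeR quasi-likelihood adjusted p lay between 3.54e-06 and 0.00251.

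Of the called genes, 2249 had groups that did not overlap, as did 36.6% of all tested genes, where chance gives 10% for 3 against 3. The count of calls fell to 861, 832, 931 and 807 without knockout library 1, knockout library 3, wild-type library 2 or wild-type library 3, and rose to 4295 without knockout library 2. Without both knockout library 2 and wild-type library 1 it was 7556, and 2249 of the 2252 calls were among them. Both fits without knockout library 2 kept knockout libraries that correlated with GC content at 0.26, against -0.03 or -0.16 in the wild-type libraries. Such fits cannot tell a GC trend from the genotype. The fit without both libraries also keeps only the closest pair of each group (3.46 and 6.29 per gene), so its spread is small. The genes changed at least 2-fold numbered 363 without knockout library 3 and 355 without wild-type library 3. The authors' deposited table calls 2495 genes under an adjusted p of 0.05, and 2116 of them were also called here.

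**Figure D2:**
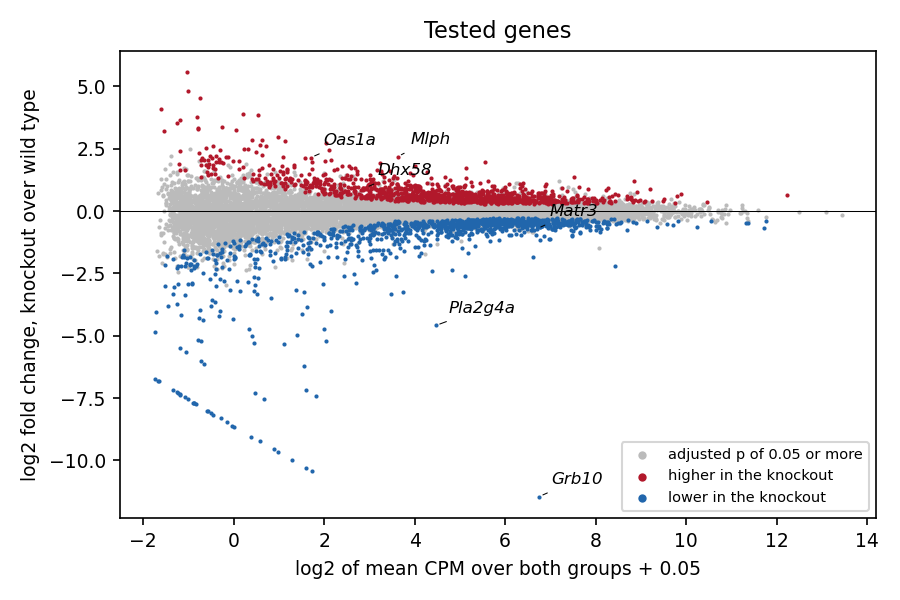
Log2 fold change of each tested gene (knockout over wild type) against the log2 of its mean CPM over both groups plus 0.05; red and blue points are called higher or lower. The 1142 rises and 1110 falls spread over the range of expression; the diagonal line of blue points is genes with no knockout reads, whose fitted fold changes depend on the prior count.

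Among genes induced by interferon that passed the expression filter, more rose than fell. The list holds 42 genes, all found in the table, and Ifit1, Ifit3 and Mx1 were among those too low to test. Of 33 tested members of the interferon-stimulated list, 15 rose, 2 fell and 16 did not pass, and adjusted over the list alone 18 rose and 2 fell (edgeR quasi-likelihood test). Named after their values were seen, Ifit2 (-0.17) and Bst2 (0.07) were among the 16. Oas1a, a sensor of double-stranded RNA that activates RNase L, rose from 1.18 ± 0.169 to 5.23 ± 0.410 CPM (log2 fold change 2.14), and the ubiquitin-like modifier gene Isg15 from 6.28 ± 0.449 to 16.8 ± 2.19 CPM (1.42; SD, n = 3 each). Oas3 (0.76) and the secreted lectin-binding protein gene Lgals3bp (0.57) rose less. The edgeR quasi-likelihood adjusted p was 0.00102, 0.00103, 0.00329 and 0.00501 for these 4 genes. Usp18, which removes Isg15 from proteins and damps interferon receptor signalling, fell by 1.09 on the log2 scale, and Samd9l, named after its value was seen, by 1.92. The call of Usp18 ended without knockout library 1 or 3 or wild-type library 2 or 3 (edgeR quasi-likelihood adjusted p from 0.0621 to 0.0789). The list's median log2 fold change was 0.57, and against all other genes camera gave an adjusted p = 4.27e-06. The call is lost with an estimated correlation (camera adjusted p = 0.465 with an estimated correlation). The medians of the 3 knockout libraries against the wild-type mean were 0.44, 0.46 and 0.57. The Oas1 genes are near-identical members of a multigene family, so the values of single Oas1 genes are uncertain.

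**Figure D3:**
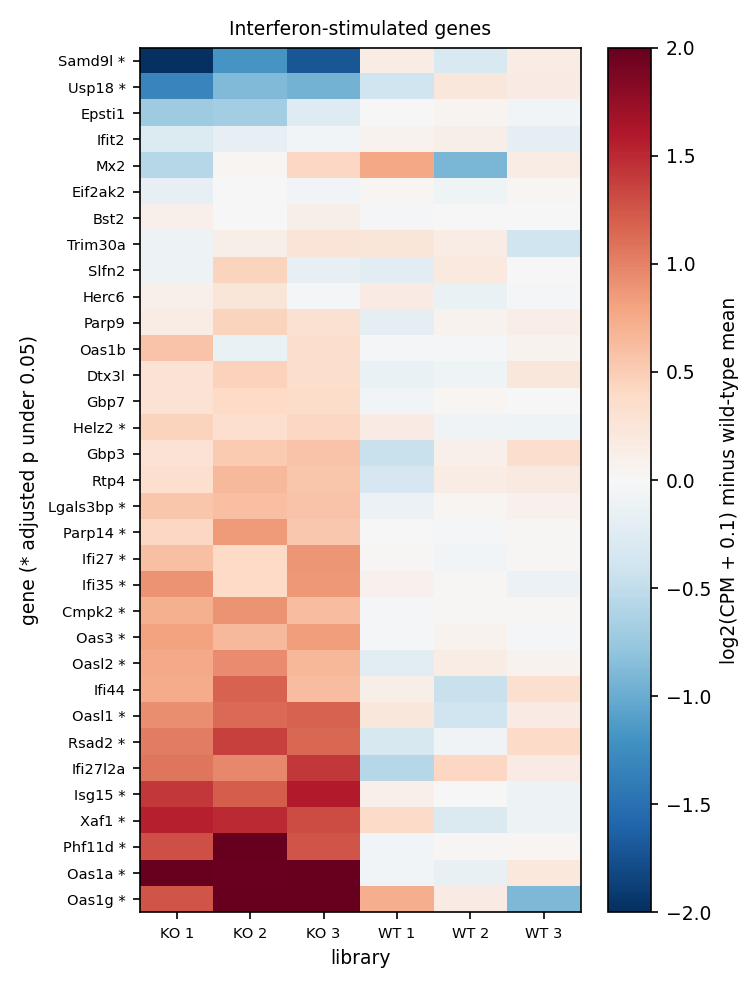
Log2(CPM + 0.1) of each tested interferon-stimulated gene in each library, minus the mean of the wild-type libraries; stars mark adjusted p under 0.05. Oas1a, Isg15 and most starred genes are higher in all 3 knockout libraries, while Usp18 and Samd9l are lower.

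Receptors of foreign RNA moved both ways. Of 24 tested genes of cytosolic RNA sensing, 4 rose, 4 fell and 16 did not pass; adjusted over the list alone, 4 rose and 5 fell (edgeR quasi-likelihood test). Ifih1, which encodes the sensor MDA5, rose from 6.95 ± 0.189 to 12.6 ± 1.25 CPM (log2 fold change 0.86), Nlrx1, a mitochondrial regulator of antiviral signalling, by 1.07 and Anxa11 by 0.57, beside Dhx58 (edgeR quasi-likelihood adjusted p = 0.00487 for Ifih1, 0.0146 for Nlrx1 and 0.00690 for Anxa11). Nlrx1 lost its call without knockout library 1 or 3 or wild-type library 2 or 3 (edgeR quasi-likelihood adjusted p from 0.0550 to 0.0679). The helicase genes Dhx33 (-0.47), Dhx15 (-0.48), Ddx3x (-0.41) and Dhx9 (-0.43), named after their values were seen, fell. The list as a whole did not pass (median 0.04, camera adjusted p = 0.665). Among 22 genes of interferons, their receptors and signalling, 4 rose and 1, Usp18, fell, with the same counts adjusted over the list alone. The transcription factors Irf7, at 4.79 ± 0.853 against 1.93 ± 0.281 CPM (1.31, edgeR quasi-likelihood adjusted p = 0.00825), and Irf1 (0.62, 0.00733) rose beside Ifnlr1 and the kinase gene Tyk2 (0.50, named after its value was seen). This list did not pass either (median 0.05, camera adjusted p = 0.146), but it passed with no filter on low counts (0.00908, range 0.00908 to 0.245 over 14 alternatives) and by fry (0.0166).

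Of 23 genes of MHC class I antigen presentation, 6 rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone (edgeR quasi-likelihood test; list median 0.06, camera adjusted p = 0.0696). The list passed camera without knockout library 1 (adjusted p = 0.0471), knockout library 2 (0.0296) or wild-type library 2 (0.0491), with no filter on low counts (0.00272; range 0.00272 to 0.180 over 14 alternatives), and by fry (0.0249). The nonclassical class I genes H2-T23 (log2 fold change 1.34, adjusted p = 0.000747) and H2-T22 (0.69, 0.00276) and the peptide editor Tapbpl (1.07, 0.00103) rose. Nlrc5, the transactivator of class I genes, fell from 12.8 ± 2.96 to 3.48 ± 0.866 CPM (-1.87; SD, n = 3 each; adjusted p = 0.00262), and B2m, the invariant light chain, by 0.47 (named after its value was seen). H2 genes belong to a multigene family, and their single values are uncertain.

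In 3 lists on stress and inflammation some genes rose and most did not pass. In the list of the unfolded protein and integrated stress responses 11 of 30 genes rose and 0 fell, and 13 rose adjusted over the list alone (edgeR quasi-likelihood test; median 0.31, camera adjusted p = 2.92e-05, and adjusted p = 0.497 with an estimated correlation). Ppp1r15a, which directs dephosphorylation of eIF2alpha, rose from 43.7 ± 4.87 to 92.9 ± 9.08 CPM (log2 fold change 1.09, adjusted p = 0.00133), Ddit3, which encodes the transcription factor CHOP, by 1.01 (0.00244) and the pseudokinase gene Trib3 by 0.92 (0.00154). Of 28 genes of oxidative stress and NRF2 targets 9 rose and 0 fell, 12 adjusted over the list alone (median 0.32, camera adjusted p = 0.00126, and adjusted p = 0.497 with an estimated correlation), with the glutathione transferase Gsta4 (1.27, edgeR adjusted p = 0.00240), the transporter Abcc3 (0.86, 0.00518) and thioredoxin reductase Txnrd1 (0.54, 0.00750). Of 26 NF-kB targets, cytokines and chemokines 5 rose and 0 fell, 8 adjusted over the list alone (median 0.26, camera adjusted p = 0.0098, and adjusted p = 0.497 with an estimated correlation). Relb, an NF-kB subunit, rose by 0.68 (edgeR adjusted p = 0.00862) and the chemokines Cxcl2 by 0.97 (0.0225) and Cxcl10 by 0.78 (0.0231); the calls of both chemokines ended without knockout library 1 or 3 or wild-type library 2 or 3 (edgeR quasi-likelihood adjusted p from 0.0534 to 0.0927). Not passed were 19, 19 and 21 genes of the stress response, NRF2 and NF-kB lists. The NF-kB list missed the threshold without knockout library 2 and wild-type library 1 (camera adjusted p = 0.0624, range 0.000226 to 0.0624 over 14 alternatives). At an unadjusted p under 0.05, 0, 1 and 1 genes of the stress response, NRF2 and NF-kB lists were lower by edgeR, and DESeq2, limma voom and limma on log2(FPKM + 1) called 0 lower in each.

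Transcripts of the mitochondrial genome fell as a list, less so in knockout library 2. The list medians against the wild-type mean were -0.51, -0.14 and -0.44 in knockout libraries 1 to 3 and -0.09, -0.05 and 0.14 in the wild-type libraries. Of 15 mitochondrially encoded genes 6 fell and 0 rose, and 8 fell adjusted over the list alone (edgeR quasi-likelihood test; median -0.38, camera adjusted p = 0.00126, and adjusted p = 0.497 with an estimated correlation). The complex I genes mt-Nd1, at 2577 ± 267 against 4166 ± 324 CPM (log2 fold change -0.69, adjusted p = 0.00696), and mt-Nd4l (-0.64, 0.00633) fell, as did cytochrome b, mt-Cytb (-0.40, 0.0329), whose call ended without knockout library 1 or 3 or wild-type library 2 or 3 (edgeR quasi-likelihood adjusted p from 0.105 to 0.135). The list's median GC content is 36.0%, against 49.6% for all tested genes, and with the GC and length trend removed its median was -0.16 and it did not pass (camera adjusted p = 0.165, range 1.38e-06 to 0.165 over 14 alternatives). None of the 15 was higher at an unadjusted p under 0.05 by edgeR, and the other tools called 0 higher and 7 (DESeq2), 6 (limma voom) and 1 (limma on log2(FPKM + 1)) lower. Histone genes of the replication-dependent list rose in 3 of 11 members, 4 adjusted over the list alone, and 0 fell (median 0.78, camera adjusted p = 0.025, adjusted p = 0.497 with an estimated correlation, and fry adjusted p = 0.0660). The 3 are H3c3 (0.73, edgeR adjusted p = 0.0319), H4c4 (1.13, 0.0448) and H1f0 (0.62, 0.0150), of which H1f0 is a linker histone made outside of replication. The list's median was 1.36 above the wild-type mean in knockout library 2, against 0.20 and 0.72 in knockout libraries 1 and 3, and the list did not pass without knockout library 2 (median 0.36, camera adjusted p = 0.148). It also missed the threshold at a mean of at least 1 CPM (0.0750), with protein-coding genes only (0.0570), with the GC and length trend removed (0.0809) and without knockout library 2 and wild-type library 1 (0.162; range 0.000531 to 0.162 over 14 alternatives). At an unadjusted p under 0.05, 6 of the 11 were higher and 0 lower by edgeR, and DESeq2, limma voom and limma on log2(FPKM + 1) each called 3 higher and 0 lower. The call of H4c4 ended without any library other than wild-type library 1 (edgeR quasi-likelihood adjusted p from 0.0726 to 0.143), that of H3c3 without knockout library 1 or 3 or wild-type library 2 or 3 (0.0951 to 0.126) and that of H1f0 without knockout library 1 or 3 or wild-type library 3 (0.0622 to 0.0656). Histone genes are a multigene family, and single values are uncertain.

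**Figure D4:**
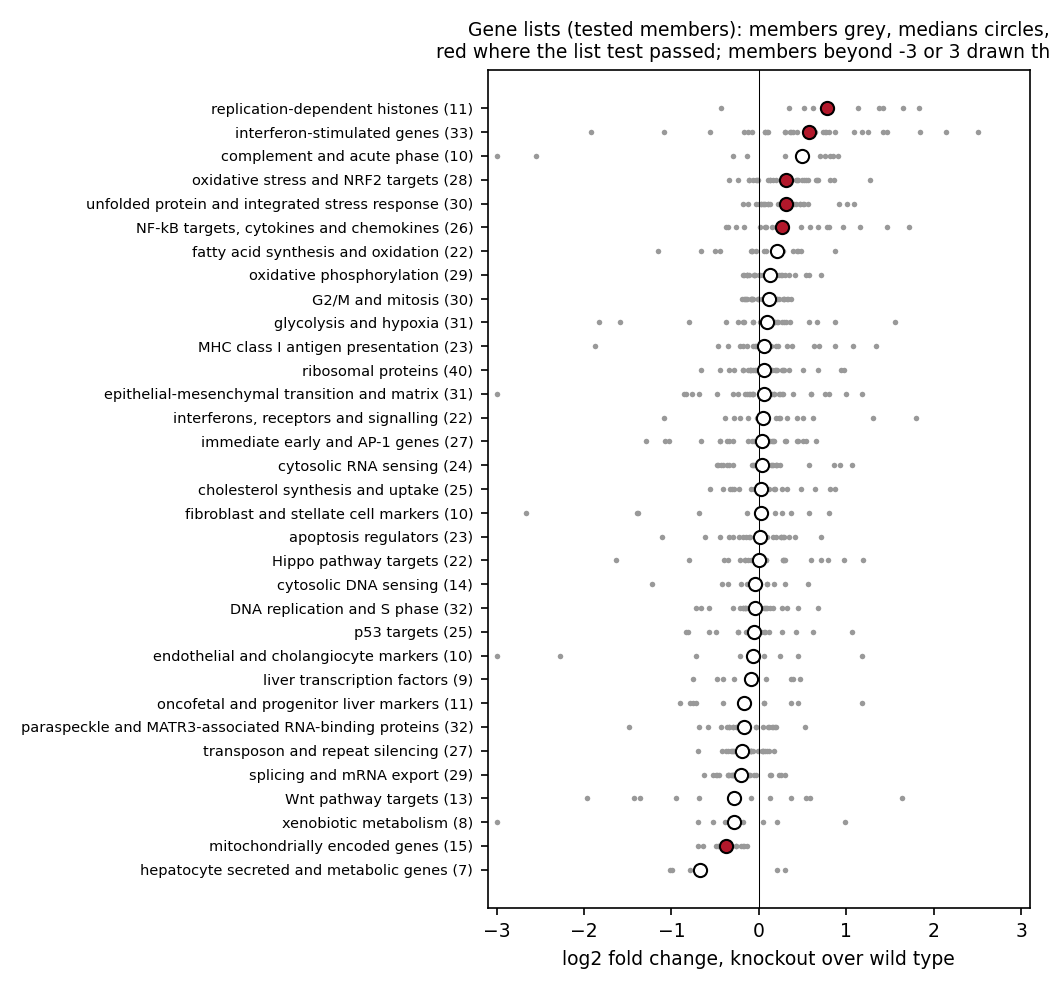
Log2 fold changes (knockout over wild type) of the tested members of 33 gene lists (grey points) and the list medians (circles), filled red for the 6 lists that passed camera with the preset correlation; the number of tested members is in brackets. The interferon-stimulated list has a median of 0.57 and the mitochondrially encoded list one of -0.38.

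In all, 6 of 33 lists passed camera with the preset correlation, 5 upward and 1 downward. With an estimated correlation 0 passed, with 1 list at an unadjusted p under 0.05, and fry called 12, which include 5 of the 6 and leave out the histone list. The other 9 splits of the 6 libraries into 3 and 3 gave 3 to 10 lists each with the preset correlation.

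Lists on RNA processing and repeat silencing lay lower without passing camera in the full set of libraries. The splicing list passed without knockout library 2 (camera adjusted p = 0.0192, range 0.0192 to 0.191 over 14 alternatives) and without wild-type library 2 (0.0270), and the silencing list passed fry with the smallest adjusted p of all lists, 0.00268. The splicing list's median GC content is 42.8%, against 49.6% for all tested genes. Its pass without knockout library 2, which leaves knockout libraries at a GC correlation of 0.26, cannot be told from a GC trend. In splicing and mRNA export 5 of 29 genes fell and 0 rose (edgeR quasi-likelihood test; 8 fell adjusted over the list alone; median -0.21), in transposon and repeat silencing 5 of 27 fell (8; median -0.19) and in paraspeckle and MATR3-associated RNA-binding proteins 5 of 32 fell (6; median -0.17), with camera adjusted p = 0.0754 for each. Higher members at an unadjusted p under 0.05 numbered 3, 0 and 0 by edgeR in these lists, and 0 in each by DESeq2, limma voom and limma on log2(FPKM + 1) at an adjusted p under 0.05. Their members named here were picked after their values were seen: Tardbp (-0.69), Ptbp2 (-0.58), Sfpq (-0.34), Rbm14 (-0.30) and Dhx9 among RNA-binding proteins; Srsf2, Srsf3, Srsf11, Nxf1 and Thoc2 in splicing and export; and Setdb1 (-0.37), Dnmt3b (-0.70), Ehmt1, Mphosph8 and Adarb1 in silencing. Of 13 Wnt targets 4 fell, Lef1 (-1.97), Tcf7 (-1.43), Znrf3 and Apcdd1, and 2 rose, Notum (1.63) and Glul (0.37), with a median of -0.28 (2 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.0754, 0.0151 without wild-type library 1, range 0.0151 to 0.183 over 14 alternatives; fry adjusted p = 0.0249).

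Metabolic lists did not pass camera with the preset correlation. By fry, glycolysis and hypoxia passed (adjusted p = 0.0249). With no filter on low counts, glycolysis and hypoxia (camera adjusted p = 0.0133, range 0.0133 to 0.433 over 14 alternatives) and oxidative phosphorylation (0.00982, range 0.00982 to 0.502) passed. Ribosomal protein genes passed upward without knockout library 2 (0.0233) and without it and wild-type library 1 (0.00776, range 0.00776 to 0.971). Their medians against the wild-type mean were 0.12, -0.14 and 0.16 in knockout libraries 1 to 3. These passes thus rest on leaving out the knockout library that was lower, and cannot be told from the GC trend of the knockout libraries kept. Among 22 genes of fatty acid synthesis and oxidation, 5 rose and 4 fell (edgeR quasi-likelihood test; 6 and 4 adjusted over the list alone; median 0.21, camera adjusted p = 0.411). Named after their values were seen, the oxidation genes Cpt1a (0.44) and Acadvl were among those that rose, with Acacb and Plin2, and the synthesis genes Fasn (-0.50), Acaca (-0.44), Elovl6 and Dgat2 fell. In cholesterol synthesis and uptake 5 of 25 rose, Mvk, Pmvk, Tm7sf2, Ebp and Acat2, and 2 fell, Insig1 and Hsd17b7 (5 and 3 adjusted over the list alone; median 0.03). In glycolysis and hypoxia 4 of 31 rose, Car9 (1.56), Ndrg1, Pfkfb4 and Pfkm, and 2 fell, Slc2a3 (-1.83) and Eno2 (4 and 3 adjusted over the list alone; median 0.09). Of 29 genes of oxidative phosphorylation, 0 passed either way, also adjusted over the list alone (median 0.12; 6 higher and 0 lower at an unadjusted p under 0.05; 1 called by DESeq2, 0 by the limma fits), and of 40 ribosomal protein genes 1 fell, Rpl35, and 0 adjusted over the list alone (median 0.06). In xenobiotic metabolism 1 of 8 rose, Adh7, and 2 fell, Cyp1a1 and Abcb1b, with the same counts over the list alone (median -0.29).

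Most growth and fate lists held genes that rose and genes that fell, and their called members are likewise named after the values were seen. In G2/M and mitosis 3 of 30 genes rose, Aurkb, Birc5 and Foxm1, and 0 fell, with 0 either way over the list alone (edgeR quasi-likelihood test; median 0.11; 6 higher and 0 lower at an unadjusted p under 0.05). DESeq2, limma voom and limma on log2(FPKM + 1) called 5, 4 and 2 of its genes higher and 0 lower, and the list passed camera with no filter on low counts (adjusted p = 0.0282, range 0.0282 to 0.993 over 14 alternatives); in DNA replication and S phase 2 of 32 rose, Rfc3 and Rfc4, and 2 fell, the cyclins Ccne1 (-0.66) and Ccne2 (-0.72), with the same counts over the list alone (median -0.05). Of 25 p53 targets 2 rose, Pmaip1 (1.06) and Plk2, and 3 fell, Aen, Zmat3 and Ccng1 (3 and 3 over the list alone; median -0.06). Of 23 apoptosis regulators 1 rose, Bmf, and 2 fell, Bcl2 (-1.11) and Bid (2 and 3 over the list alone; median 0.01). Of 27 immediate early genes 3 rose, Klf4, Atf3 and Phlda1, and 5 fell, Egr1 (-1.03), Egr3, Klf2 (-1.30), Jun and Dusp5 (4 and 6 over the list alone; median 0.04). Of 22 Hippo targets 3 rose, Amotl2, Gadd45b and Foxf2, and 3 fell, Fjx1, Nt5e and Asap1 (5 and 3 over the list alone; median 0.01). Of 31 genes of epithelial-mesenchymal transition and matrix 5 rose, Tgfbi (1.18), Snai2 (1.00), Thbs1, Col1a1 and Col6a1, and 4 fell, Fn1 (-0.86), Zeb2 (-0.84), Mmp9 and Mmp2, the last with 0 knockout reads and at least 47.2-fold lower (5 and 4 over the list alone; median 0.06, the same with Mmp2 at its bound). Of 14 genes of cytosolic DNA sensing 1 rose, Ifi204, and 2 fell, Aim2 and Ifi209 (2 and 2 over the list alone; median -0.04).

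Many liver and cell type markers were too low to test. Only 7 of 37 hepatocyte genes found in the table were tested, of which 2 fell, Rbp4 (-0.99) and Arg1 (-0.63; edgeR quasi-likelihood test; 4 fell over the list alone; median -0.67, camera adjusted p = 0.121, fry adjusted p = 0.0142). Of 11 oncofetal and progenitor markers 1 rose, Krt19 (1.18), and 4 fell, Hmga2 (-0.90), Spp1 (-0.75), Sox4 and Igf2bp1 (1 and 5 over the list alone; median -0.17), and of 9 liver transcription factors Gata6 fell (-0.47; 1 over the list alone; median -0.09). In complement and acute phase 2 of 10 rose, C3 (0.85) and C1ra, and 2 fell, among them Lbp (-2.54; 4 and 2 over the list alone; median 0.50). Among fibroblast and stellate cell markers 3 of 10 rose, Col1a1 (0.81), Des and Pdpn, and 2 fell, Pdgfrb (-1.39) and Dpt (3 and 3 over the list alone; median 0.02). Among endothelial and cholangiocyte markers 1 of 10 rose, Krt19, and 3 fell, Aqp1, Cdh5 (-2.27) and Eng (1 and 3 over the list alone; median -0.07, fry adjusted p = 0.0142). Only 2 of 22 leukocyte markers were tested, Cd68 and Coro1a, and neither passed (edgeR; 1 at an unadjusted p under 0.05, 0 by DESeq2 or the limma fits). Where no list value is given for the metabolic, growth, fate and marker lists, the camera adjusted p lay between 0.146 and 0.860. The median, mean and test differ in sign for the lists of apoptosis regulators, epithelial-mesenchymal transition and matrix, immediate early genes, complement, and fibroblast markers.

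Neighbouring genes shifted together in some regions. In windows of 40 neighbouring genes, 16 of 277 had a median log2 fold change at least 0.2 from that of all genes. Of these, 9 lay on chromosome 11 between 68876523 and 121607132, among 15 windows of this stretch, whose other 6 windows were higher by 0.11 to 0.19 and so under that distance. The stretch as a whole holds 595 tested genes over the windows' expression limit, with a median of 0.22, of which 152 rose and 19 fell (edgeR quasi-likelihood test). Dhx58, Lgals3bp and Abcc3 lie in this stretch. Its start is set by the distance of 0.2. The adjoining windows, from 53150641 to 68797815, were higher by 0.19, 0.16 and 0.17, so the raised region may begin earlier. Irf1, at 53660841 to 53669200, lies among these adjoining windows. Chromosome 10 between 80864372 and 82733546 had a median of 0.55 over 40 genes, of which 17 rose and 0 fell by edgeR, and holds Glt8d2 and Txnrd1. Chromosome 2 between 37333291 and 84481109 had a median of -0.25 over 120 genes, of which 5 rose and 30 fell, and holds Ifih1. Single windows on chromosomes 5, 13 and 18 were lower. Against the wild-type mean, the medians in knockout libraries 1 to 3 were 0.26, 0.13 and 0.26 for the chromosome 11 stretch, 0.68, 0.36 and 0.60 for chromosome 10, and -0.31, -0.12 and -0.30 for chromosome 2, where wild-type library 1 was at -0.09. The windows on chromosomes 13 and 18 were not shifted in knockout library 2 (0.02 and -0.02, against -0.27 and -0.25, and -0.22 and -0.24, in knockout libraries 1 and 3).

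**Figure D5:**
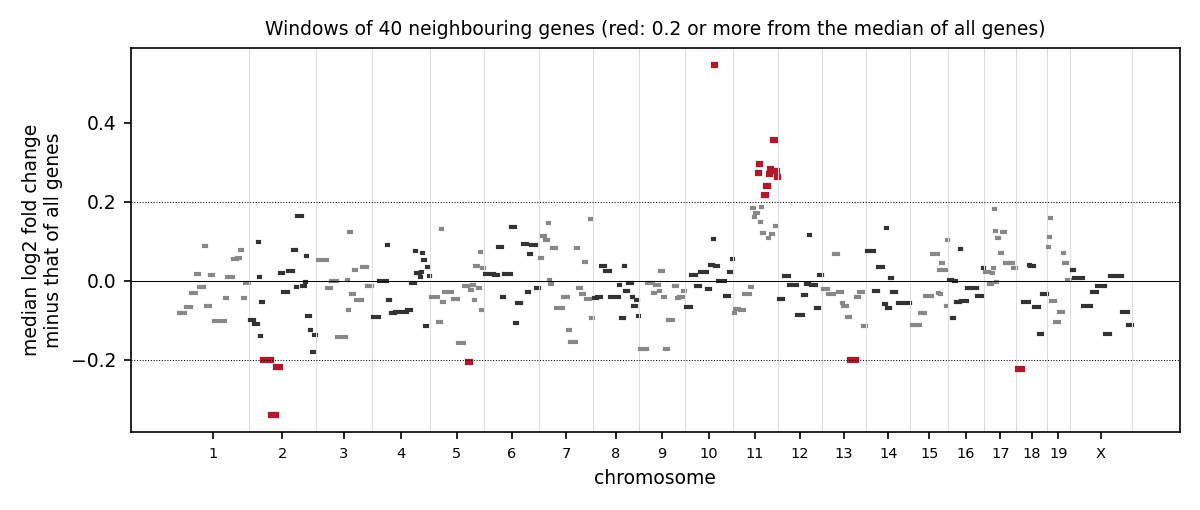
Median log2 fold change (knockout over wild type) of each window of 40 neighbouring genes minus the median of all genes, along the chromosomes; red windows lie at least 0.2 from 0 and dotted lines mark that distance. The chromosome 10 window stands at 0.55 and 9 windows of chromosome 11 lie above 0.2.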

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

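The added settings, which are the removal of the GC and length trend and the fit without knockout library 2 and wild-type library 1, were chosen after the data were seen; the others were fixed before. Matr3 and Dhx58 kept their direction and their call in 34 of 34 tests, 17 settings each, at log2 fold changes of -0.78 to -0.53 and 0.64 to 1.08. The median of the interferon-stimulated list ranged from 0.47 to 0.63, and the list passed camera with the preset correlation in 14 of 14 alternatives, but not with an estimated one (adjusted p = 0.465 with an estimated correlation). Leaving out each library in turn gave 807 to 4295 changed genes and 355 to 726 changed at least 2-fold, against 2252 and 564. An adjusted p under 0.01 left 721 genes. Without the 2 libraries that stand apart 7556 genes changed, 1076 at least 2-fold. With no filter on low counts 903 genes changed at least 2-fold and 11 lists passed, against 6, and limma on log2(FPKM + 1), a scale that shrinks the change of low genes, gave 96 genes at least 2-fold. With an estimated correlation 0 lists passed and fry called 12. The cause of these shifts was not tested. A smaller number of libraries or a stricter threshold can lower a count, but would not by itself raise it to 4295 or 7556. Those counts came without knockout library 2, alone or together with wild-type library 1, the libraries furthest from their groups. The knockout libraries kept in both fits correlated with GC content at 0.26, so these fits cannot tell a GC trend from the genotype. The replicate numbers do not pair the libraries: the correlations of deviations for numbers 1, 2 and 3 were 0.17, -0.03 and -0.20. With the replicate block 1599 genes were called, 1534 of them among the 2252. With the GC and length trend removed 3005 genes were called, including 2061 of the 2252, and 4 lists passed; the mitochondrial and histone lists did not. DESeq2 called 2516 genes, 2111 of them among the 2252. Over the named genes, 725 of 765 values kept their side of the threshold and 40 fell short of it, with 0 reversed. The named genes were picked from these same libraries for large or clear changes, and all were called in the main fit. A high share kept was therefore nearly fixed in advance and is no independent check. Over the list medians 442 of 462 kept their side, 7 fell short and 13 came past it. Library totals alone moved the median by 0.02. A 1.5-fold change was recovered in 37.3% of simulated genes, so small changes can be missed. With 200 changed genes simulated and 2252 called here, that share does not carry over to these data. Of the called genes, 706 had a log2 fold change under 0.5 in size.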

Other observations

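Of the tests below, those of gene order, of Dhx58 against its stretch, of library depth, of silent against newly active genes, of imprinted genes, of the rises outside shifted windows, and the splits for 2-fold changes and gene lists were chosen after the result was seen.

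A set of genes was near silent in the knockout libraries. Of the called genes, 43 had at most 3 reads over the 3 knockout libraries, 39 of them protein-coding, against 4 with at most 3 reads over the wild-type libraries. Named after their values were seen, Pcdh19, a protocadherin, had 0 reads against 487 and was at least 181-fold lower, Fbn2, which encodes fibrillin 2, at least 167-fold lower and the zinc finger gene Zfp449 at least 131-fold lower. The imprinted gene Peg3 had 3 reads against 519, a 193-fold ratio with a counting interval of 65.6 to 938. Grb10, also imprinted, had 6 against 16133, a 2998-fold ratio with an interval of 1377 to 8171. The 4 genes near silent in the wild type were Cdh10, Itgal, Calhm5 and Cldn23. An unannotated feature on chromosome 2, 75468721 to 75473219, fell from 564 ± 50.6 to 121 ± 4.62 CPM (SD, n = 3 each; log2 fold change -2.22, edgeR quasi-likelihood adjusted p = 5.09e-05).

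The splits of the 6 libraries into 3 and 3 are 10, too few for a share under 0.05. The real split gave 2252 changed genes and the highest of the others 0 by edgeR (78 to 2387 at an unadjusted p under 0.05), so 1 of 10 splits reached the real count, as for 2-fold changes (564 against a highest of 0). Each other split has knockout and wild-type libraries on both sides, so a difference between the groups adds to its spread and lowers its count. The count of 0 is therefore no level for libraries without such a difference. For gene lists, 6 of the 10 splits gave at least the 6 lists of the real split, and the highest gave 10. The largest chromosome median, that of chromosome 11, lay 0.15 from the median of all genes, within the 0.2 set as the bound for a change in copy number of a whole chromosome.

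The interferon-stimulated list had a median of 0.57 and passed camera with the preset correlation, a call that is lost with an estimated one (adjusted p = 0.465 with an estimated correlation). With the GC and length trend removed its median was 0.48 (bootstrap SD 0.11) and it passed camera with the preset correlation, which argues against that trend as the whole cause. Its 30 members outside shifted windows had a median of 0.42 (bootstrap SD 0.15), above a bound of 0.3 by less than that spread, so a part from copy number blocks stays open. Of the 30, 12 rose, against 7.06% of the 13972 other genes outside the windows (two-sided Fisher exact p = 4.18e-07). This argues against the shifted windows as the cause of every rise. The Fisher test takes genes as independent, which members of a list need not be, and smaller or weaker blocks are not covered. The real split gave a list p of 1.29e-07 by camera with the preset correlation and the smallest of the others was 4.46e-06, so 1 of 10 splits reached it, where 10 are too few for a share under 0.05. The other splits also mix knockout and wild-type libraries on both sides, so they give no level for libraries without a group difference. A response to the Matr3 knockout stays open as a hypothesis, as does a difference between cultures that the design does not separate from the knockout.

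Blocks of neighbouring genes that shifted together may reflect copy number differences between the knockout and wild-type cultures, which a tumour line can gain during cloning. The 16 shifted windows exceeded the highest of 100 shuffles of gene order, 2, and 11 remained with the GC and length trend removed, again against a highest of 2, which argues against chance order and against that trend as the whole cause. Dhx58 lay 4.56 of its own SE above the median of 0.22 of the other genes in its chromosome 11 stretch. That SE measures the spread between libraries and not the scatter of genes within the stretch, where 152 of 595 rose and 19 fell. Dhx58 was also chosen from the series title and not at random. The distance therefore cannot decide whether a gain of that stretch alone gave its rise. DNA copy number was not analysed here, and coordinated regulation of these regions stays open.

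A descent of the knockout cultures from one founder cell or a few, in which such genes happened to be off, was not tested independently. The ratio of silent to newly active genes, 10.8 (43 against 4), is the observation that raised this hypothesis and decides nothing on it. The knockout libraries held 1.10 times the reads of the wild-type libraries, which argues against depth. The nearest tested genes on both sides of silent genes had a median log2 fold change of -0.14 (bootstrap SD 0.08). Of these 86 neighbours, 7 were called lower by edgeR and 0 were near silent themselves. This argues against deletions that span several genes as the general cause, but cannot exclude them at some of the silent genes. Of 24 tested imprinted genes 8 changed, 7 of them downward (two-sided Fisher exact p = 0.0211), but without Grb10 and Peg3, which prompted this test, 6 of 22 changed, 27.3% against 15.1% of other genes (p = 0.131), so an excess of imprinted genes stays undecided. A founder effect and silencing that follows from the Matr3 knockout itself both stay open.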
